A study of Rosa rugosa with 9 samples.

How the data were processed

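Polyadenylated RNA from young roots was sequenced as paired reads of 150 bases on an Illumina NovaSeq instrument, per the labels' protocols. The authors deposited 1 table with a whole-number count and an FPKM value per gene and library, per the file headers. The steps from reads to counts ran on the Biocloud platform, per the labels. The aligner, the counter, the genome build and the strand setting are not given in the sources used here. The authors' deposited table also holds adjusted p-values and log2 fold changes from DESeq2 at an FDR of 0.01 and a fold of 2, per the file headers. The deposited FPKM values were not used in any test. The table lists 47983 genes, of which 13758 had 0 counts in every library and 23524 had a Swiss-Prot description. Gene names were taken from the descriptions in the table, since 0 of its gene IDs matched the RefSeq gene table. No coordinates were printed.

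Samples were grouped by the labels into CK, HA1 and HA2 with 3 libraries each. Total counts ranged from 33847262 to 42988605. Before TMM scaling 3 counts correspond to 0.0698 to 0.0886 CPM. With TMM scaling they correspond to 0.0637 CPM in CK replicate 1 and 0.0903 CPM in HA1 replicate 2. Replicate numbers were not treated as pairs. Of 9 pairs of libraries with the same number, 3 had a correlation over 0.1 after group means were removed. These were the pairs of CK with HA2, at 0.12, 0.11 and 0.32 for replicates 1 to 3. In all, 3 of 9 libraries correlated best with their own number.

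Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 9 libraries. The comparisons were HA1 with CK, HA2 with CK and HA2 with HA1, each two-sided, with Benjamini-Hochberg adjustment over 25260 genes and a threshold of 0.05. SE values are the absolute log2 fold change over the square root of the F statistic. CPM values are scaled by TMM. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated. The 40 gene lists, matched by words in the descriptions, needed at least 5 tested members. KEGG pathways from the deposited annotation needed 10 to 500. The lists, comparisons, thresholds and alternatives were chosen before the data were examined, except where the text says otherwise.

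The named genes were, per comparison, the 10 with the largest increase and the 10 with the largest decrease among genes past the threshold with a description that names a function, a mean of at least 5 CPM in the higher group and no overlap between the groups. The 3 members with the lowest p of each list were added, and the 5 genes with the lowest p where fewer than 5 passed. The text prints a selection of these, made after their values were seen.

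The shared response of HA1 and HA2 was set against 100 simulations that drew all 9 libraries from the CK means with the fitted dispersions. This simulation was chosen after the data were seen, because one that kept the CK counts and drew the others from their means left out the chance error of the CK libraries. Alternatives were size factors by median ratios (RLE), the DESeq2 1.42.0 Wald test, no filter beyond a count above 0, at least 1 CPM in at least 3 libraries, only the 6 libraries of the 2 groups, a block for replicate number, a log2 fold change of at least 1, and leaving out each of the 9 libraries in turn. DESeq2 without HA2 replicate 3, and the shared response without it, were added after the data were seen. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.

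The procedure was tested on simulated data with 200 changed genes, drawn from the means and library sizes of the real samples. For HA1 against CK, with 24758 genes in the step, it recovered 7% of genes changed 2-fold and 72% of those changed 4-fold, and 6 of 85 calls were genes not changed. For HA2 against CK, with 24726 genes, it recovered 1% at 2-fold and 75% at 4-fold, with 3 of 79 calls not changed. For HA2 against HA1, with 24723 genes, it recovered 5% at 2-fold and 74% at 4-fold, with 4 of 83 calls not changed. In each comparison camera found the 1 shifted list of 10 and no other. Each simulated gene was drawn independently, so this cannot show how camera behaves where the members of a list vary together. In the real data the estimated correlation was 0.61 for ribosomal proteins and 0.48 for starch synthesis.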

Results

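RNA was sequenced from young roots of Rosa rugosa 'Zizhi', an ornamental rose, after 37 weeks of pot culture in sand with a weekly nutrient solution of 200 ml per pot. The 9 libraries fell into 3 groups of 3. CK plants received 0.092 g of ammonium dihydrogen phosphate and no humic acid. HA1 plants received 0.0552 g of the phosphate salt with 0.0368 g of humic acid, which is 60% of the control phosphorus. HA2 plants received 0.0368 g of the salt with 0.0552 g of humic acid, which is 40% of the control phosphorus. Phosphorus supply fell as humic acid rose, and ammonium from the salt fell with it, so no comparison separates the 3. Each library held 33847262 to 42988605 counts. The 10 most abundant genes took 4.55% to 5.71% of them. The labels do not state that replicates are separate plants, so p-values measure the spread between these samples.

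The first principal component carried 43.9% of the variance of log2 CPM and set the CK libraries, at -131 to -42.3, apart from the HA1 libraries, at 67.7 to 70.4. HA2 replicates 1 and 2 lay at 66.3 and 39.7, near HA1, and HA2 replicate 3 lay at -45.8, within the CK range. It was not CK-like on the next components, which carried 15.3% and 11.5% of the variance. On the second it lay at -79.6, where CK lay at 4.3 to 33.1 and HA2 replicates 1 and 2 at 39 and 56.7. On the third it lay at -67.1, where CK lay at -20.9 to 39.5. Both values of HA2 replicate 3 were the lowest of the 9 libraries. Several gene groups stood apart in that library. The median of the abscisic acid and jasmonate list, relative to the mean of all 9 libraries, was 0.72 and 0.66 in HA2 replicates 1 and 2 and -0.16 in replicate 3. For purple acid phosphatases it was 0.45 and 0.36 against -0.11, for lignin and phenylpropanoid synthesis 0.32 and 0.50 against -0.42, and for starch synthesis -0.22 and -0.22 against 0.49.

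**Figure D1:**
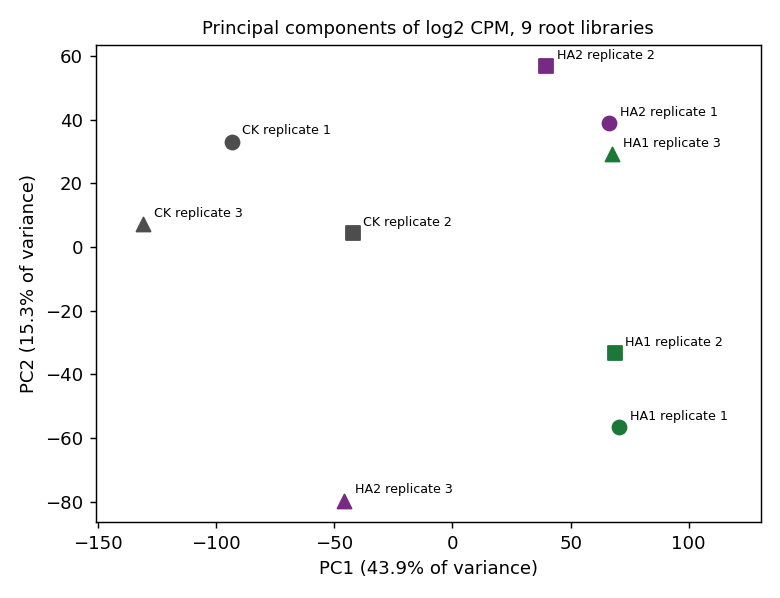
Principal components of log2 CPM for the 9 root libraries, with the share of variance on each axis, group by colour and replicate by symbol. HA2 replicate 3 lies at -45.8 on the first axis, apart from HA2 replicates 1 and 2 at 66.3 and 39.7.

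The comparison of HA1 with CK asks how roots respond to a moderate replacement of phosphate by humic acid. Single genes tied to phosphate changed in both directions. The phosphate exporter PHO1 homolog 1 (Rru04G046980) fell by 2.07 ± 0.38 (log2 fold change ± SE, n = 3 per group), from 26.7 ± 8.44 to 6.35 ± 2.33 CPM (mean ± SD), and the phosphate sensor SPX domain-containing protein 4 (Rru02G073540) fell by 1.63 ± 0.29. Among purple acid phosphatases, which release phosphate from organic compounds, purple acid phosphatase 20 (Rru03G021690) rose by 2.71 ± 0.44 and purple acid phosphatase 18 (Rru05G032070) by 1.51 ± 0.28. Monogalactosyldiacylglycerol synthase (Rru06G050530), an enzyme of galactolipid synthesis, rose by 3.01 ± 0.81, from 56.3 ± 40.0 to 453 ± 43 CPM. Both chains of ATP-citrate synthase, which makes acetyl-CoA from citrate, rose, the beta chain (Rru04G036720) by 2.23 ± 0.51 and the alpha chain (Rru04G052080) by 1.95 ± 0.55. Ammonium transporter 3 member 1 (Rru03G031940) rose by 3.42 ± 0.56, a near copy (Rru03G031890) by 3.37 ± 0.58, and ammonium transporter 1 member 1 (Rru04G008850) by 1.05 ± 0.23. The metal chelator gene nicotianamine synthase (Rru03G008300) fell by 2.34 ± 0.29. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these genes had adjusted p from 0.00911 to 0.037. Counts of near-identical tandem copies, such as the ammonium transporter pair, are uncertain because the counting of shared reads is not given. None of these calls was kept without CK replicate 1. Purple acid phosphatase 20 and nicotianamine synthase were kept in 8 of 9 leave-one-out settings. Their adjusted p, by edgeR or DESeq2, was at most 0.0506 in any alternative setting. Monogalactosyldiacylglycerol synthase and the ATP-citrate synthase alpha chain were kept in 4 of 9, with at most 0.109 and 0.115.

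**Figure D2:**
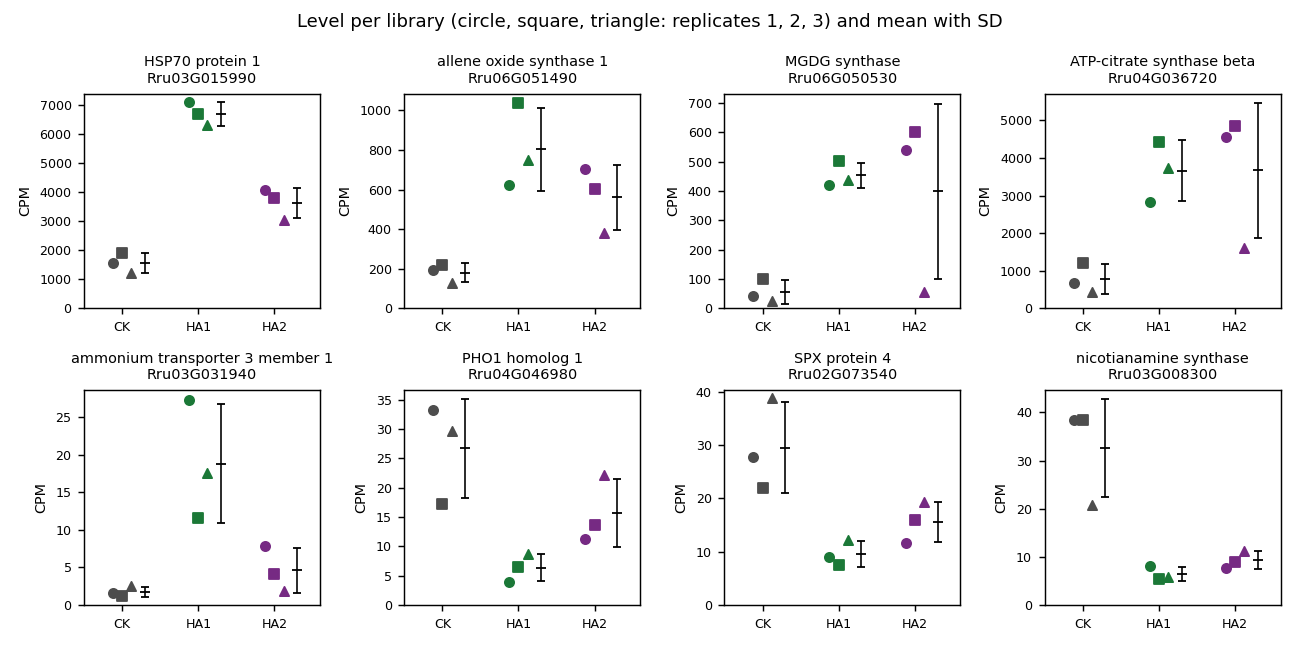
CPM of 8 named genes in each library (symbols for replicates 1 to 3) with the mean and SD of each group of 3. Heat shock 70 kDa protein 1 lay at 1560 ± 345 CPM in CK and 6690 ± 400 in HA1, and SPX domain-containing protein 4 at 29.5 ± 8.55 and 9.54 ± 2.38.

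Single members of the stress and hormone lists passed in HA1, although those lists did not pass camera. The chaperones heat shock 70 kDa protein 1 (Rru03G015990) and protein 4 (Rru01G042900) rose by 2.10 ± 0.28 and 1.78 ± 0.21. Allene oxide synthase 1 (Rru06G051490), of jasmonate synthesis, rose by 2.15 ± 0.33 and the abscisic acid receptor PYL4 (Rru03G012080) by 1.42 ± 0.25. Gibberellin 2-beta-dioxygenase 2 (Rru03G034020), which inactivates gibberellin, rose by 3.49 ± 0.65, and by 3.12 to 4.6 over the alternative settings. The calcium pumps calcium-transporting ATPase 8 (Rru04G012260) and 10 (Rru04G012050) rose by 1.55 ± 0.23 and 1.86 ± 0.32. Transcription factor MYB123 (Rru06G055700) fell by 2.21 ± 0.20 and CASP-like protein 2B1 (Rru05G000730), of a family that includes barrier proteins of the endodermis, fell by 1.49 ± 0.16. Among the largest decreases, 2 RPW8-type powdery mildew resistance genes (Rru07G047020 and Rru07G047010) fell by 4.23 ± 0.82 and fell by 4.01 ± 0.74, the nitrate and peptide transporter family member NRT1/PTR 5.9 (Rru02G075500) fell by 3.89 ± 0.50, and a 3-hydroxy-3-methylglutaryl-CoA reductase gene (Rru06G033660) fell by 3.55 ± 0.72. UDP-glycosyltransferases 74B1 (Rru04G054460) and 82A1 (Rru02G062150) rose by 5.54 ± 1.5 and 5.14 ± 1.41, from 2.40 ± 3.84 to 110 ± 38.4 CPM and from 7.73 ± 7.65 to 272 ± 155 CPM. In CK the first of these lay at 0.297, 6.83 and 0.0706 CPM, and its log2 fold change was 9.13 without CK replicate 2 and 4.94 without CK replicate 3. That of the second was 6.22 without CK replicate 2 and 4.57 without HA1 replicate 3. Leaving out each library in turn, the first call was kept in 3 of 9 settings and the second in 4. The edgeR adjusted p of these genes ranged from 0.00672 to 0.0344. None of these calls was kept without CK replicate 1. Heat shock 70 kDa protein 1, allene oxide synthase 1, PYL4 and MYB123 were kept in 8 of 9 leave-one-out settings. Their adjusted p, by edgeR or DESeq2, was at most 0.0506 in any alternative setting. The log2 fold change of heat shock 70 kDa protein 1 stayed between 1.92 and 2.22.

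A group of genes was near 0 in CK and present in some HA1 libraries. Low affinity inorganic phosphate transporter 4 (Rru01G053270) lay at 0.149, 0 and 0 CPM in the CK libraries, at 34.2, 7.85 and 0.344 CPM in HA1 and at 18.7, 0.666 and 18.6 CPM in HA2. The cysteine protease gene SAG39 (Rru02G042080) lay at 0.127, 0 and 0 CPM in CK, 29.3, 6.38 and 0.804 in HA1, and 11.2, 0.721 and 23.8 in HA2. On the TMM scale of these values a count of 3 was 0.0637 CPM in CK replicate 1 and 0.0903 CPM in HA1 replicate 2. Without TMM it was 0.0698 to 0.0886 CPM over the libraries. This floor covers counting error only, since the reads carry no molecular identifiers. In HA1 against CK their edgeR adjusted p was 0.0286 and 0.0242, and neither call was kept without CK replicate 1.

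Of 25260 genes tested, 5355 differed between HA1 and CK by edgeR, 2761 higher and 2594 lower in HA1, and 3737 of them by a log2 fold change of at least 1. Of these calls 5111 had an adjusted p between 0.01 and 0.05, and the lowest was 0.00672. The 3 values of the groups did not overlap in 11370 genes (45%, where chance gives 10%). With all libraries, 9704 genes had an unadjusted p under 0.05 by edgeR and DESeq2 called 7619 genes. The edgeR count was 0 without CK replicate 1, 666 without CK replicate 3, 1675 without HA1 replicate 1, 823 without HA1 replicate 2 and 2422 without HA1 replicate 3. In the authors' deposited table, DESeq2 called 1961 genes higher and 1916 lower, at an FDR of 0.01 and a fold of 2. Of those 3877 calls 3314 also passed edgeR with the same sign. DESeq2 as rerun here gave 1806 higher and 1753 lower at those thresholds.

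Among the 40 gene lists fixed in advance, 2 passed camera in HA1 against CK. Starch synthesis was lower, with a median log2 fold change of -0.89. Of its 11 genes, 0 rose, 4 fell and 7 did not pass over all genes, and 4 fell adjusted over the list alone. They included starch synthase 4 (Rru05G011500), which fell by 1.38 ± 0.29, and the small subunit of glucose-1-phosphate adenylyltransferase (Rru02G063190), which fell from 309 ± 95.7 to 99.6 ± 23.1 CPM. The starch list had an adjusted p of 0.0244, and adjusted p = 0.8 with an estimated correlation. Ribosomal proteins were higher, with a median of 0.26. Of 195 genes, 9 rose, 1 fell and 185 did not pass, and 0 rose and 0 fell adjusted over the list alone. That list had an adjusted p of 0.00928, and adjusted p = 0.8 with an estimated correlation. Scaled by total count, which moved the median of all genes to -0.30, the ribosomal median was -0.04, which is 0.26 above that of all genes, against 0.27 with TMM. The ribosomal call ended without CK replicate 1 (0.122), CK replicate 3 (0.0826) or HA1 replicate 1 (0.364). Its median was 0.16, 0.17 and 0.06 in these settings, and 0.40 without CK replicate 2. The starch call ended without CK replicate 1 (0.105), CK replicate 3 (0.0826) or HA1 replicate 3 (0.0952). Its median stayed at -0.84, -0.85 and -0.85 there.

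The lists tied to phosphorus, hormones and stress did not pass camera in HA1 against CK. Of 24 phosphate transporters 6 rose, 3 fell and 15 did not pass, with 6 up and 3 down adjusted over the list alone. Of 27 purple acid phosphatases 6 rose, 0 fell and 21 did not pass, with 7 up and 1 down adjusted over the list alone. Of 7 SPX domain proteins 0 rose, 2 fell and 5 did not pass, with 0 up and 2 down adjusted over the list alone. Of 66 abscisic acid and jasmonate genes 15 rose, 8 fell and 43 did not pass, with 19 up and 9 down adjusted over the list alone. Of 118 ethylene genes 21 rose, 14 fell and 83 did not pass, with 24 up and 14 down adjusted over the list alone. Of 83 auxin genes 6 rose, 16 fell and 61 did not pass, with 6 up and 18 down adjusted over the list alone. Of 104 endodermis and suberin markers 5 rose, 16 fell and 83 did not pass, with 5 up and 16 down adjusted over the list alone. Of 87 heat shock proteins 17 rose, 9 fell and 61 did not pass, with 22 up and 14 down adjusted over the list alone. Of 621 disease resistance proteins 88 rose, 50 fell and 483 did not pass, with 98 up and 53 down adjusted over the list alone. Of 67 glutathione S-transferases 1 rose, 9 fell and 57 did not pass, with 0 up and 8 down adjusted over the list alone. Of 48 genes in the list of plasma membrane proton pumps 9 rose, 2 fell and 37 did not pass, with 12 up and 3 down adjusted over the list alone. All 9 that rose and both that fell were calcium-transporting, and of the 14 proton pumps in it 0 rose and 0 fell by edgeR. Over all genes, 0 members of these lists passed without CK replicate 1, where 0 of all genes tested passed.

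Of 120 KEGG pathways, 1 passed camera in HA1 against CK. The gene set annotated as betalain biosynthesis was lower, with a median log2 fold change of -1.89. Of 19 members 1 rose, 8 fell and 10 did not pass, with 2 up and 11 down adjusted over the list alone. Those that fell included zinc-finger homeodomain protein 11 (Rru04G050200) and mini zinc finger protein 2 (Rru07G004320), which are not enzymes of pigment synthesis. The others that fell were described as uncharacterized proteins. The member that rose was an extradiol ring-cleavage dioxygenase (Rru02G049380). A second such gene (Rru02G032930), at 1.19, and tyrosine decarboxylase 2 (Rru06G038130), at -0.42, did not pass edgeR. The set therefore does not show lower pigment synthesis. The pathway had an adjusted p of 0.00717, and adjusted p = 0.98 with an estimated correlation. It passed without any 1 of the 9 libraries (highest adjusted p = 0.0261, without HA2 replicate 3). The member calls, named here after their values were seen, were 0 without CK replicate 1, where 0 of all genes tested passed.

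The comparison of HA2 with CK asks how roots respond to the larger replacement. The gene for probable inactive receptor kinase At2g26730 (Rru02G076220) rose by 3.58 ± 0.34, from 0.581 ± 0.132 CPM in CK to 6.95 ± 1.34 in HA2 (n = 3 per group), with 3.80 ± 1.23 in HA1. It was the 1 gene of 25260 that passed edgeR, with an adjusted p of 0.0485, and it did not pass with a block for replicate number. Several phosphate and hormone genes had large fold changes without passing. Purple acid phosphatase 17 (Rru07G000950), a phosphate-releasing enzyme, was at 20.8 ± 8.90 CPM in CK, 23 ± 15.7 in HA1 and 91.1 ± 36.8 in HA2. The lipoxygenase gene linoleate 13S-lipoxygenase 2-1 (Rru01G000790) was at 4.40 ± 1.60, 61.3 ± 21.7 and 191 ± 173 CPM in the same order. Their edgeR adjusted p were 0.134 and 0.132. At an unadjusted p under 0.05 edgeR gave 5233 genes, and DESeq2 gave 2189 genes at an adjusted p under 0.05. The values of the groups did not overlap in 5511 genes (21.8%, where chance gives 10%). The edgeR count was 1421 without CK replicate 2 and 1834 without HA2 replicate 3, and it was 0 without any 1 of the other libraries. In the authors' deposited table, DESeq2 called 280 genes higher and 94 lower in HA2, at an FDR of 0.01 and a fold of 2. Of those 374 calls 1 passed edgeR with the same sign. DESeq2 as rerun here gave 524 higher and 107 lower at those thresholds.

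In HA2 against CK 11 of the 40 lists passed camera, although 0 of their members passed edgeR over all genes. Abscisic acid and jasmonate genes were higher, with a median log2 fold change of 0.97 and an adjusted p of 1.05e-05, and adjusted p = 0.52 with an estimated correlation. Of these 66 genes, 19 were up and 1 down adjusted over the list alone. Purple acid phosphatases were higher (median 0.81, adjusted p = 0.000424, and adjusted p = 0.491 with an estimated correlation), with 7 of 27 up and 0 down adjusted over the list alone. Phosphate transporters were higher (median 0.61, adjusted p = 0.00173, and adjusted p = 0.491 with an estimated correlation), with 7 of 24 up and 0 down adjusted over the list alone. The mean of that list was 1.33. It includes transporter 4 (Rru01G053270 and Rru01G053280) and transporter 8 (Rru01G047790), which were near 0 in CK and in HA2 replicate 2. Their log2 fold changes were 7.77, 8.18 and 4.78. Terpenoid synthesis was higher (median 0.62, adjusted p = 0.00558, and adjusted p = 0.52 with an estimated correlation), with 13 of 35 up and 0 down adjusted over the list alone. Ethylene genes were higher (median 0.48, adjusted p = 0.000999, and adjusted p = 0.664 with an estimated correlation), with 0 of 118 up and 0 down adjusted over the list alone. Green tissue markers were lower (median -0.66, adjusted p = 0.000999, and adjusted p = 0.52 with an estimated correlation), with 0 of 45 up and 0 down adjusted over the list alone. The list of plasma membrane proton pumps was higher (median 0.59, adjusted p = 0.00173, and adjusted p = 0.523 with an estimated correlation), with 5 of 48 up and 0 down adjusted over the list alone. Its 34 calcium-transporting members had a median of 0.72 and its 14 proton pumps a median of 0.14. These 7 lists passed without any 1 of the 9 libraries, but their medians moved. The ethylene median was 0.29 without CK replicate 3, with an adjusted p of 0.0123, and the terpenoid median 0.39 without HA2 replicate 2, with an adjusted p of 0.0326. The purple acid phosphatase median was 0.54 without HA2 replicate 2, the abscisic acid and jasmonate median 0.69 and the pump median 0.40 without CK replicate 3, the phosphate transporter median 0.49 without HA2 replicate 1, and the green tissue median -0.54 without CK replicate 1.

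The other 4 lists past camera in HA2 against CK depended on single libraries. Lipid remodelling under low phosphorus was higher (median 0.45, adjusted p = 0.0093, and adjusted p = 0.536 with an estimated correlation), with 4 of 26 up and 0 down adjusted over the list alone. It did not pass without CK replicate 2 (0.0534) or HA2 replicate 2 (0.07). Disease resistance proteins were higher (median 0.14, adjusted p = 0.027, and adjusted p = 0.768 with an estimated correlation), with 0 of 621 up and 0 down adjusted over the list alone. They did not pass without CK replicate 2 (0.0762), CK replicate 3 (0.0982) or HA2 replicate 3 (0.0525). Glycolysis was higher (median 0.16, adjusted p = 0.027, and adjusted p = 0.666 with an estimated correlation), with 1 of 57 up and 0 down adjusted over the list alone. It did not pass without CK replicate 3 (0.16), HA2 replicate 2 (0.065) or HA2 replicate 3 (0.0531). Aquaporins were higher (median 0.67, adjusted p = 0.0375, and adjusted p = 0.536 with an estimated correlation), with 3 of 22 up and 0 down adjusted over the list alone. They did not pass without CK replicate 3 (0.0982), HA2 replicate 2 (0.101) or HA2 replicate 3 (0.0531).

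Among KEGG pathways, alpha-linolenic acid metabolism, the route to jasmonate, was higher in HA2 than in CK (median 0.46, adjusted p = 0.00134, and adjusted p = 0.799 with an estimated correlation). Photosynthesis antenna proteins were lower (median -1.12, adjusted p = 0.00134, and adjusted p = 0.799 with an estimated correlation) and the citrate cycle was higher (median 0.21, adjusted p = 0.00587, and adjusted p = 0.799 with an estimated correlation). By camera 15 of 120 pathways passed, 12 higher and 3 lower. The number was 9 without CK replicate 2 and 6 without CK replicate 3.

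**Figure D3:**
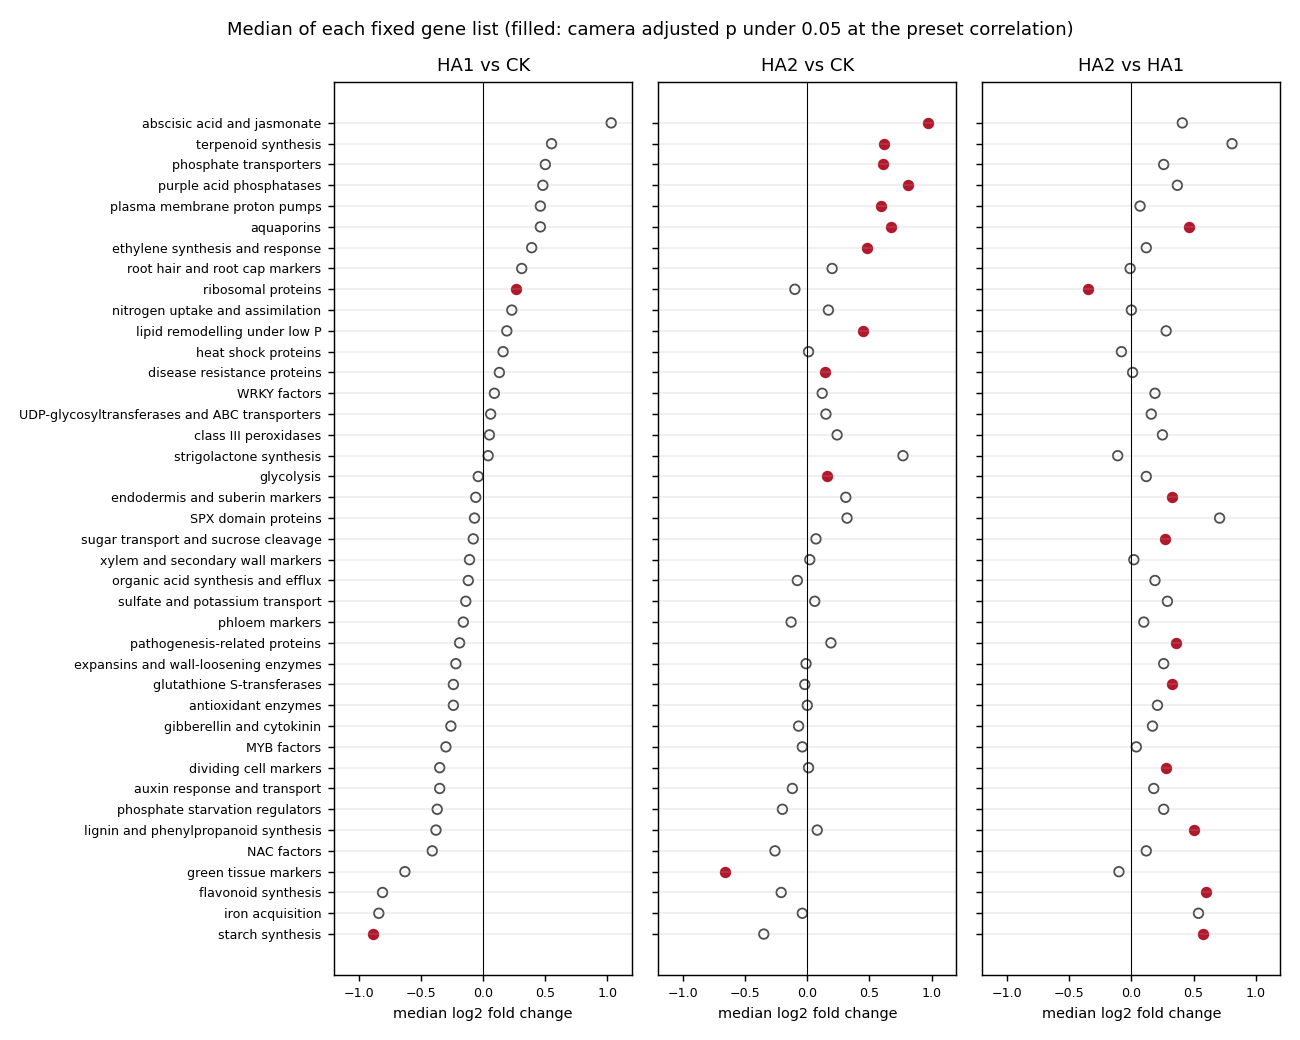
Median log2 fold change of each of the 40 fixed gene lists in the 3 comparisons, filled where camera with the preset correlation gave an adjusted p under 0.05. The abscisic acid and jasmonate list had medians of 1.03 in HA1 and 0.97 in HA2 against CK.

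HA1 and HA2 share the CK libraries, so their fold changes against CK are related by construction. Of the 5355 genes called in HA1, 5185 (96.8%) had the same sign in HA2, with a median absolute log2 fold change of 1.28 in HA1 and 0.66 in HA2. These genes were picked on the same CK libraries, which raises that share. They were also picked as changed in HA1, which raises the HA1 median and not the HA2 median in the same way. The HA2 values include replicate 3, which lay within the CK range on the first principal component. The 2 medians therefore do not measure how much smaller the HA2 response is. Across 25260 genes, which are not independent replicates, the log2 differences of HA1 and HA2 had r = 0.80 and a covariance of 0.67. Counts simulated for all 9 libraries from the same means, with no treatment effect, gave r = 0.50 (0.47 to 0.51) and a covariance of 0.115 (0.107 to 0.12). The covariances differed by 0.55. The same sign was found in 79.1% of genes and in 66.6% of simulated genes (66% to 67.6%). The simulation drew genes independently and leaves out factors that move many genes of a library together. Its ranges are therefore too narrow to show how far chance can reach. The 3 CK libraries cannot be divided into 2 sets of at least 2, so part of the excess can come from the shared controls.

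The comparison of HA2 with HA1 asks whether the larger replacement differs from the smaller. The genes with the lowest p had lower means in HA2 than in HA1. Transcription factor bHLH157 (Rru07G008430) was at 9.57 ± 1.25 CPM in CK, 21 ± 3.01 in HA1 and 5.92 ± 1.64 in HA2. A dehydration-responsive element-binding protein gene (Rru06G057100), of a family of stress regulators, was at 33.6 ± 10.1, 77.9 ± 7.26 and 21 ± 3.31 CPM, and cyclic nucleotide-gated ion channel 1 (Rru01G018140) at 21 ± 2.94, 59.3 ± 5.93 and 25.1 ± 2.83 CPM (n = 3 per group). None passed edgeR, with adjusted p of 0.176 each. By DESeq2 all 5 genes with the lowest p, these among them, passed at an adjusted p under 0.05, also without HA2 replicate 3. Of 25260 genes edgeR called 0, with 4069 at an unadjusted p under 0.05, and DESeq2 called 947. The values did not overlap in 6133 genes (24.3%, where chance gives 10%). In the authors' deposited table, DESeq2 called 89 genes higher and 123 lower in HA2, at an FDR of 0.01 and a fold of 2. Of those 212 calls 0 passed edgeR with the same sign. DESeq2 as rerun here gave 72 higher and 97 lower at those thresholds.

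In HA2 against HA1 10 of the 40 lists passed camera, 9 higher and 1 lower in HA2, although 0 of their members passed edgeR over all genes. Ribosomal proteins were lower (median -0.35, adjusted p = 1.97e-10, and adjusted p = 0.673 with an estimated correlation), with 0 of 195 up and 0 down adjusted over the list alone. They passed without any 1 of the 9 libraries, but without HA1 replicate 1 the median was -0.14, with an adjusted p of 0.00141. Relative to the mean of all 9 libraries the list median was 0.56, 0.13 and -0.11 in HA1 replicates 1 to 3 and -0.04, -0.32 and -0.05 in HA2, so HA1 replicate 3 lay below HA2 replicates 1 and 3. Lignin and phenylpropanoid synthesis was higher (median 0.50, adjusted p = 0.0103, and adjusted p = 0.673 with an estimated correlation), and phenylalanine ammonia-lyase 1 (Rru01G039610), its entry enzyme, was at 533 ± 49.5 CPM in CK, 316 ± 42.4 in HA1 and 535 ± 77.9 in HA2. Flavonoid synthesis was higher (median 0.60, adjusted p = 0.0265, and adjusted p = 0.673 with an estimated correlation), with 3 of 37 up and 1 down adjusted over the list alone. Starch synthesis was higher (median 0.58, adjusted p = 0.0279, and adjusted p = 0.673 with an estimated correlation). Glutathione S-transferases, endodermis and suberin markers, aquaporins, dividing cell markers, pathogenesis-related proteins and sugar transport were also higher, with medians from 0.27 to 0.46. Adjusted over the list alone 1 aquaporin was up, 1 pathogenesis-related protein was up and 1 down, and 0 members of the other lists named without such a count passed. None of the 10 lists passed with an estimated correlation (adjusted p = 0.673 for each). Without HA2 replicate 3, starch synthesis did not pass (0.192), with a median of 0.18. Without HA2 replicate 2, the calls for lignin and phenylpropanoid synthesis (0.404), endodermis and suberin markers (0.237), sugar transport (0.237), aquaporins (0.159) and glutathione S-transferases (0.0624) ended. Without HA1 replicate 2, those for dividing cell markers (0.221), pathogenesis-related proteins (0.121), endodermis and suberin markers (0.0778), aquaporins (0.0778) and sugar transport (0.0778) ended. Without HA1 replicate 1, sugar transport (0.143) and starch synthesis (0.0527) did not pass. Without HA1 replicate 3, starch synthesis (0.139) and dividing cell markers (0.0519) did not pass, and without CK replicate 3, sugar transport (0.0514) did not. Without HA2 replicate 1 ribosomal proteins were the 1 list of 40 that passed, and the other 9 had adjusted p from 0.0686 to 0.512. In that setting the median was 0.30 for lignin and phenylpropanoid synthesis, 0.35 for flavonoid synthesis and 0.07 for dividing cell markers. For starch synthesis it was 0.52 there. The lignin and phenylpropanoid median was 0.26 without HA2 replicate 2. The number of lists was 5 without HA1 replicate 2, 5 without HA2 replicate 2 and 17 without HA2 replicate 3. Among KEGG pathways 18 of 120 passed, led by ribosome, which was lower (median -0.31, adjusted p = 2.22e-05, and adjusted p = 0.714 with an estimated correlation), and steroid biosynthesis, which was higher (median 0.52, adjusted p = 2.22e-05, and adjusted p = 0.551 with an estimated correlation). The ribosome pathway did not pass without HA1 replicate 1 (0.0623). The number of pathways was 8 without HA2 replicate 1 and 29 without HA2 replicate 3.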

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

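The tests of a CK plant, of sequencing depth and of single libraries in the ribosomal difference of HA2 from HA1 were chosen after the result was seen. Each of 10 gene lists drew attention because the change from CK differed between HA1 and HA2, tested directly as HA2 against HA1 by camera with the preset correlation. Adjusted p was 1.97e-10 for ribosomal proteins, 0.0103 for glutathione S-transferases and 0.0103 for lignin and phenylpropanoid synthesis. It was 0.0265 for endodermis and suberin markers and 0.0265 for flavonoid synthesis. It was 0.0279 for aquaporins, 0.0279 for starch synthesis, 0.0279 for dividing cell markers and 0.0279 for pathogenesis-related proteins, and 0.0408 for sugar transport and sucrose cleavage. With an estimated correlation none passed, with adjusted p = 0.673 for each. The 6 libraries of HA1 and HA2 make 10 splits into 3 and 3, too few for a share under 0.05. Each number of splits that gave as many includes the real split. For lists the real split gave 10, the highest other gave 16, and 3 splits gave as many. For pathways the real split gave 18, the highest other 23, and 3 splits gave as many. For genes the real split and the highest other both gave 0 by edgeR, in 10 of 10 splits, with 4069 genes at an unadjusted p under 0.05 and 947 by DESeq2.

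The splits of the 6 libraries of each comparison with CK are also 10, too few for a share under 0.05. The numbers of splits as large again include the real split. For HA1 against CK the real split gave 5355 genes and the highest other 0, so only the real split gave as many. Its lists were 2 against a highest other of 10, with 9 splits as large, and its pathways 1 against 13, with 9 splits as large. For HA2 against CK the real split gave 1 gene and the highest other 1, with 2 splits as large. Its lists were 11 against a highest other of 12, with 2 splits as large, and its pathways 15 against 9, with 1 split as large.

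HA2 replicate 3 lay apart from HA2 replicates 1 and 2. Lower depth is argued against by its total of 42988605 counts, the highest of the 9 libraries. A CK plant in its place stays open: 68.2% of 44 genes below 1 CPM in every CK library reached 1 CPM in it, while each CK library, left out of that choice in turn, reached it in 12% of 50 genes (replicate 1), 48.8% of 86 (replicate 2) and 2.2% of 45 (replicate 3). RNA mixed from a CK and an HA2 plant should put no more genes outside all other libraries than other libraries have. In HA2 replicate 3, 409 genes lay at least 2-fold outside them. This was above every other library (from 123, and 404 in HA1 replicate 1) except CK replicate 3, at 648. A mixture stays open, since the count was not above each other library. A difference between plants of the group was not tested.

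The ribosomal protein list was higher in HA1 than in CK and lower in HA2 than in HA1 by camera with the preset correlation, but did not pass with an estimated correlation (adjusted p = 0.8 and 0.673). A shared factor in single libraries may carry the first difference, because the lowest HA1 median minus the highest CK median was -0.35 and the call ended without CK replicate 1 (0.122), CK replicate 3 (0.0826) or HA1 replicate 1 (0.364). Single libraries as the cause of the second difference stay open: the lowest HA1 median minus the highest HA2 median was -0.07, and the median log2 fold change of -0.35 became -0.14 without HA1 replicate 1 (adjusted p = 0.00141), whose list median of 0.56 was the highest of the 9, while the middle HA1 library, at 0.13, lay above the HA2 libraries. Scaling shifts all genes of a library alike and so does not move the list relative to them: the list lay 0.27 above the median of all genes with TMM and RLE and 0.26 with total counts. Whether its level rose in absolute terms stays open, since its median was -0.04 when scaled by total count. A response to humic acid or phosphorus stays open.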

How the results depend on the processing

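DESeq2 and the shared response without HA2 replicate 3 were chosen after the data were seen. No result listed here changed direction, and the cause was not tested where a count moved. RLE size factors gave 5359, 1 and 0 genes for HA1 against CK, HA2 against CK and HA2 against HA1. For HA2 against CK the 1 gene became 0 with at least 1 CPM in at least 3 libraries, with only the 6 libraries of the 2 groups, and with the replicate block. The replicate block gave 5206 genes for HA1 against CK and 0 for HA2 against HA1, where 4069 had an unadjusted p under 0.05 by edgeR. DESeq2 gave 2189 genes for HA2 against CK and 947 for HA2 against HA1, and without HA2 replicate 3 it gave 8690, 4448 and 471 for the 3 comparisons. With the correlation estimated 0 lists and 0 pathways passed camera in each comparison, with a lowest adjusted p of 0.491.

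Leaving out each library in turn gave 0 to 7003 genes for HA1 against CK, 0 to 1834 for HA2 against CK and 0 to 0 for HA2 against HA1. Lists ranged over 0 to 3, 9 to 13 and 1 to 17, and pathways over 1 to 1, 6 to 17 and 8 to 29. The shared response, run only without each CK replicate and without HA2 replicate 3, ranged from r = 0.76 to 0.84 across genes. Of 134 named calls in HA1 against CK, 134 were kept by DESeq2, 134 with RLE, 132 with no filter and 128 with the replicate block. Without CK replicate 1 0 were kept and 0 changed direction. Without CK replicate 3 55 were kept, without HA1 replicate 1 84, HA1 replicate 2 60 and HA1 replicate 3 107. With 3 libraries per group the simulated recovery of 2-fold changes was 7%, 1% and 5% in the 3 comparisons.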

Other observations

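The tests of carried-over reads and of the symbiosis families without germin-like proteins were chosen after the result was seen, and the symbiosis families and triterpenoid genes after their patterns were noticed. A few genes of triterpenoid synthesis were abundant in these roots. A beta-amyrin synthase gene (Rru02G057740) rose by 1.52 ± 0.46 in HA1 against CK, from 2470 ± 1650 to 7100 ± 1370 CPM, and was at 6290 ± 766 in HA2. A beta-amyrin 28-monooxygenase gene (Rru04G000360) rose by 1.34 ± 0.34, from 2640 ± 964 to 6710 ± 1240 CPM, and was at 6550 ± 941 in HA2. A squalene monooxygenase SE1 gene (Rru04G031570) fell by 2.26 ± 0.65, from 207 ± 39.4 to 43.1 ± 30.5 CPM, and was at 257 ± 209 in HA2. These 3 genes had edgeR adjusted p of 0.0457, 0.0265 and 0.0389 in HA1 against CK. The less abundant SE1 genes Rru04G031580 and Rru02G023300 also fell (edgeR adjusted p = 0.0418 and 0.045). More abundant SE1 genes did not pass. Rru06G004010 was at 843 ± 376 CPM in CK and 627 ± 193 in HA1 (edgeR adjusted p = 0.464). Rru06G004050 was at 571 ± 276 and 828 ± 113 (0.292). Of 51 genes with triterpenoid descriptions 5 rose and 6 fell in HA1 by edgeR (n = 3 per group). None of these calls was kept without CK replicate 1. In HA2 against CK 0 of the 51 passed edgeR, with 18 at an unadjusted p under 0.05 and 11 by DESeq2.

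Genes near 0 in every CK library and present in some HA libraries included phosphate transporter 4 (Rru01G053270), whose relatives in other plants serve arbuscular mycorrhiza. The half-size transporter genes STR (Rru07G001290) and STR2 (Rru07G039500), the lipid enzyme gene RAM2 (Rru02G075040) and ammonium transporter 2 member 5 (Rru06G049920) followed it across libraries. STR was at 0.255, 0 and 0 CPM in CK, 8.90, 2.92 and 0.144 in HA1, and 3.80, 0.250 and 23.1 in HA2. A candidate explanation is a root symbiosis programme that was active in some plants: 13 of 125 members of 12 symbiosis families had r over 0.9 with transporter 4, against a mean of 0.533 and a highest count of 5 in 10000 random lists matched on expression. They lay in 5 families. These held 5 of 28 germin-like proteins with neighbouring IDs (Rru05G039940 to Rru05G040020), 2 of 15 acyltransferases of the RAM2 type and 2 of 4 half-size transporters. They also held 2 of 19 genes grouped as LysM receptor kinases and 2 of 6 ammonium transporters. Both LysM genes (Rru02G068770 and NewGene_7180) were described as lysM domain-containing proteins, not as receptor kinases. In 7 families no member had such an r: 0 of 12 GRAS regulators, 0 of 5 thioesterases of the FatM type, 0 of 2 vapyrin proteins, 0 of 2 calcium/calmodulin kinase and CYCLOPS genes, 0 of 13 EXO70 genes, 0 of 10 strigolactone and apocarotenoid genes and 0 of 9 monosaccharide transporters. Without the ammonium transporters, some of which had been seen before, the count was 11, and without the germin-like proteins 8, against a highest count of 4 in random lists. The random lists do not allow for tandem copies that vary together. The families of the first genes seen, such as SAG39, were left out.

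Reads carried over from HA1 replicate 1 are argued against for HA2 replicates 1 and 3, for which the test was set. Over 44 genes their median levels were 50.2% and 98.5% of that in HA1 replicate 1. The share was 2.5% in HA1 replicate 3, 2.6% in HA2 replicate 2 and 2.1% in CK replicate 1, against 0.1% and 0% in CK replicates 2 and 3. For these low levels carried-over reads stay open, since the genes lie near the floor there and were chosen as low in CK. In HA1 replicate 2 the share was 25.2%, with 40 of the 44 genes at 1 CPM or more, which also argues against carried-over reads there. The 44 genes were those below 1 CPM in every CK library and at 5 CPM or more in HA1 replicate 1, and a stricter choice had left too few genes. The labels state no inoculation, colonisation was not measured, and rose gene counts cannot show fungal reads, so this remains a hypothesis found and tested on the same data.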
